A study of Mus musculus with 27 samples.

How the data were processed

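RNA from mature 3T3-L1 adipocytes was measured on 27 Affymetrix Mouse Gene 1.1 ST arrays, 3 for untreated cells at time 0 and 3 for each of 8 times after 1 µM rosiglitazone was added, from 30 min to 48 h. Per the labels, the drug was dissolved in DMSO, and the RNA was purified with TRIzol and a silica column. The series' design text mentions cells given DMSO, but 0 of the samples used here carry that label, so the untreated arrays served as the control at every time. The deposited values are log2 intensities per probe set. Per the submitters' processing notes, Partek and RMA, a method that corrects background, normalises and summarises probes, were used, without versions or the role of each. The values ran from 1.67 to 13.19, array medians from 4.02 to 4.13, and 0 pairs of arrays were identical. Arrays give no count of molecules, and their number limits the precision.

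The table held 28815 probe sets. The annotation supplied for them named genes for 23020 probe sets, of which 1867 carried several symbols and 21153 carried 1, and the other 5795 carried none. Entrez identifiers matched 21123 of the probe sets with 1 symbol to the reference gene table, and 0 symbols changed. Where a gene had several probe sets (1367 genes), the set with the highest mean over the 27 arrays was kept, which gave 18781 genes. No filter on dim genes was applied. The genome build behind the array annotation was not given in the sources used here, so no coordinates are printed.

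Group means of the 27 arrays were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), without covariates. Each time was set against untreated, and 6 h against 2 h, 24 h against 6 h, 48 h against 24 h and 48 h against 2 h. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes of a comparison, and genes with an adjusted p below 0.05 were called. The moderated F-test of limma over the 8 comparisons with untreated gave the genes that changed over the course. A further contrast, the mean of 24 h and 48 h minus the mean of 12 h and 36 h, looked for alternation between exposure times 12 h apart. Genes called higher at 1 h or 2 h were followed to 48 h. Overlaps between times were set beside the number expected per direction, the product of the 2 counts divided by the genes tested, and beside 20 simulations of unchanged groups. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

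A total of 22 gene lists with 476 entries, 48 of them not measured, were written from general knowledge before the data were examined, as were the comparisons, tests and most alternatives. They covered PPARγ targets of lipid handling, thermogenic genes, mitochondrial and peroxisomal fatty acid oxidation, de novo lipogenesis, cholesterol synthesis, inflammatory and acute-phase genes, adipokines, extracellular matrix, immediate early genes, the circadian clock, preadipocyte and fibroblast markers, cell cycle, oxidative phosphorylation, branched-chain amino acid breakdown, adipocyte transcription factors, insulin signalling, lipolysis, glucocorticoid-responsive genes, interferon response, unfolded protein and amino acid stress, and reference genes. Some genes are in several lists. Cfd, Gyk, Dbp, Nr1d1 and Adrb3 were not analysed here, since no probe set carried their symbol alone. Each list was tested at each time with camera at a preset correlation of 0.01, which compares its genes with all others, with adjustment over lists and times. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, were alternatives. Random lists matched on mean expression were drawn 10000 times.

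Genes are named by a rule fixed in advance: per comparison up to 10 with the highest and 10 with the lowest change among called genes whose 3 arrays of a group lay beyond all 3 of the other, up to 4 members of a list with the smallest p, and a fixed panel. Separation of 3 arrays from 3 arises by chance in 10% of genes. Genes named outside this rule are said to be so. In simulated data with 100 genes changed by each amount at 48 h, 78% of changes of 0.5 and 99% of changes of 1 on the log2 scale were called at 48 h against untreated among 18781 genes, with 16 false calls beside 177 true ones. The 9 simulated contrasts without the changed group gave 0 false calls. The simulated genes were drawn independently of each other and few were changed, so these rates may not hold for the real arrays.

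Alternatives planned in advance were the replicate number as a block, genes above the median mean (4.76) alone, the mean of a gene's probe sets, centring each array on its median, a further quantile normalization, a trended and robust variance, array weights, a minimum change of 1.5-fold, models without replicate 1, 2 or 3 of every group, and models of the 6 arrays compared. Added after the results were seen were leaving out single arrays, the 30 min arrays as the baseline, leaving out the 36 h group, and removing the trend from the alternation. A list of hypoxia-responsive genes was also added then. Arrays of the same replicate number shared no common shift on average: their residuals in different groups correlated at -0.12. The residuals of a group cancel out, so the 0.061 for different numbers largely follows from that value and is no separate comparison. The numbers still held structure. On the second axis of a principal component analysis (11.7% of the variance), replicates 1, 2 and 3 rose in order at each time from 30 min to 6 h. At 2 h they lay at 2.80, 5.72 and 8.69. They fell in order at 24 h, 36 h and 48 h (-6.56, -10.14 and -13.21 at 48 h). The untreated and 12 h arrays kept no such order. The groups themselves also rose on this axis up to 6 h and fell later, so the order ran with the time course. A mean correlation does not show an effect that changes direction with time.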

Results

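Gene expression was measured in mature 3T3-L1 adipocytes, fat cells differentiated in culture from a mouse preadipocyte line, before and during exposure to 1 µM rosiglitazone. Rosiglitazone is an insulin-sensitising drug that activates PPARγ, the nuclear receptor that drives fat cell genes. The 27 arrays formed 9 groups of 3: untreated cells at time 0, and cells harvested after 30 min, 1 h, 2 h, 6 h, 12 h, 24 h, 36 h and 48 h. Log2 intensities ran from 1.67 to 13.19, and the array medians lay between 4.02 and 4.13. Changes below are log2 fold changes ± SE with n = 3 arrays per group and limma adjusted p-values, and a gene rose or fell where the adjusted p was below 0.05. The untreated arrays at time 0 were the only control, so time in culture and handling were not separated from the drug. The p-values measure the spread between these arrays, which may be technical, since the labels do not say whether the replicates were separate cultures. The number of arrays limits the precision, and the median SE of a change was 0.088.

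The question of the time course was which adipocyte genes answer to PPARγ activation, and when. A total of 7613 of 18781 genes changed over the course by the limma F-test. Against untreated cells, 9 genes changed at 30 min, 186 at 1 h, 1110 at 2 h, 3111 at 6 h, 3542 at 12 h, 3879 at 24 h, 4022 at 36 h and 4515 at 48 h. Most changes were small: 810 of the genes called at 48 h changed at least 1.5-fold and 186 at least 2-fold, and the median size of the called changes was 0.36. The genes called at 48 h comprised 2372 that rose and 2143 that fell. Centring each array on its median moved the share of rising genes among those called from 50.6% to 76.5% at 6 h and from 52.5% to 65.9% at 48 h. A further quantile normalization left that share near the main one, at 52.15% at 6 h and 50.9% at 48 h. The balance of rising and falling genes therefore depends on which scaling is used, so directions below are given for named genes and lists.

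**Figure D1:**
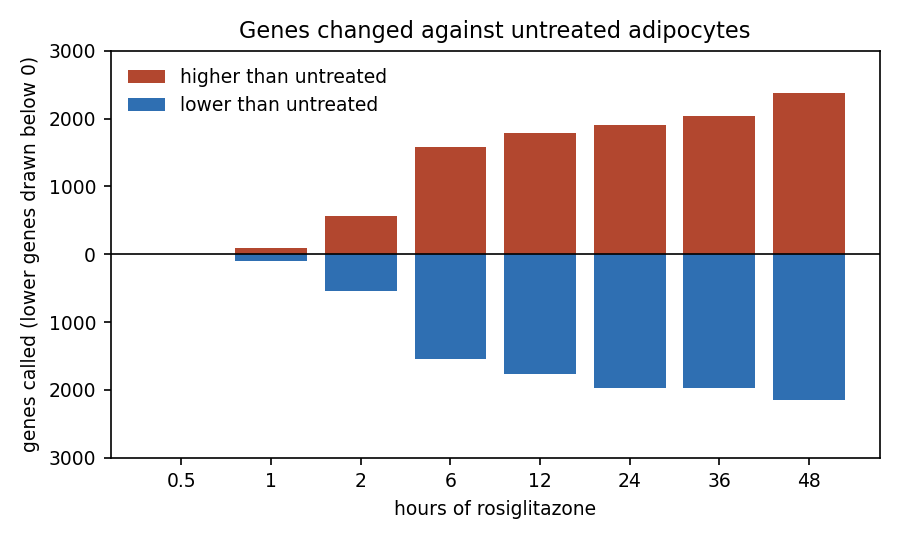
Number of genes called higher (above 0) or lower (below 0) than in untreated adipocytes at each time of rosiglitazone exposure, in hours, with 3 arrays per group. The bars grow from 9 genes at 30 min, all higher, to 2372 higher and 2143 lower genes at 48 h.

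At 30 min, the 9 genes that changed all rose. Rasl11b, a small GTPase of the Ras family, rose by 0.91 ± 0.11 (adjusted p = 0.000115), and Id3, an inhibitor of basic helix-loop-helix factors, rose by 0.85 ± 0.12 (adjusted p = 0.000841). Angptl4, a secreted inhibitor of lipoprotein lipase and a PPAR target, was already higher by 0.54 ± 0.073 (adjusted p = 0.000841). The others were the mitochondrial carrier Slc25a25, the guanine nucleotide exchange factor Rasgef1b, the Wnt receptor Fzd5, the Hippo pathway protein Amotl2, and the immediate early genes Zfp36 and Btg2. Among the 25 measured immediate early genes, which answer quickly to serum and stress, Zfp36 and Btg2 rose and 23 did not change, while 5 rose adjusted over the list alone. That list was higher by camera (adjusted p = 9.64e-05, and adjusted p = 0.104 with an estimated correlation). The count was 3 when only the 6 arrays compared entered the model. Without any 1 of the 6 arrays compared, it was between 6 and 12. In models without replicate 1, 2 or 3 of every group, which leave 2 arrays per group, the call of Angptl4 ended (adjusted p = 0.109, 0.115 and 0.0557), while its change was 0.53, 0.58 and 0.52. The calls of Zfp36, Btg2 and Slc25a25 also ended in each of these 3 models. Those of Rasgef1b, Fzd5 and Amotl2 ended without replicate 1 and without replicate 3, and that of Id3 without replicate 2 (0.87, adjusted p = 0.212), while Rasl11b was called in each.

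By 1 h, 89 genes had risen and 97 had fallen. Rasgef1b reached 1.88 ± 0.094 (adjusted p = 1.98e-12), Fzd5 1.19 ± 0.083 (adjusted p = 1.81e-09) and Angptl4 0.92 ± 0.073 (adjusted p = 1.45e-08). Pck1, the glyceroneogenic enzyme that supplies glycerol for fat storage, rose by 0.84 ± 0.11 (adjusted p = 0.000109). Ddit4, a stress-induced inhibitor of mTORC1, had the largest decrease, -1.499 ± 0.17 (adjusted p = 5.01e-06). Dusp6 and Errfi1, which restrain MAP kinase and EGF receptor signalling, changed by -1.09 ± 0.17 and -1.05 ± 0.095 (adjusted p = 0.000689 and 1.44e-07). Angptl8, an insulin-induced lipoprotein lipase inhibitor, changed by -0.91 ± 0.12 (adjusted p = 7.75e-05). The number of changed genes rested on single arrays: it was 96, 122 and 109 without untreated replicate 1, 2 or 3, and 82 without the 1 h replicate 3. With the 30 min arrays as the baseline it was 117. The call of Dusp6 ended without replicate 3 of every group (-1.11, adjusted p = 0.102).

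At 2 h, 571 genes rose and 539 fell. Pck1 rose by 1.45 ± 0.11 (adjusted p = 5.12e-09), and Pfkfb3, which makes the main activator of glycolysis, rose by 1.25 ± 0.10 (adjusted p = 7.77e-09). Angptl4 rose by 1.11 ± 0.073 (adjusted p = 2.81e-10) and Pdk4, a brake on glucose oxidation, by 0.69 ± 0.11 (adjusted p = 0.000108). Usp18, a protease that limits interferon signalling, rose by 1.32 ± 0.13 (adjusted p = 3.02e-07). Irs2, an adaptor of the insulin receptor, rose by 0.72 ± 0.077 (adjusted p = 5.75e-07), and Ucp3, a mitochondrial uncoupling protein homologue, by 0.89 ± 0.10 (adjusted p = 1.42e-06). Pparg itself fell by 0.63 on the log2 scale (SE 0.049, adjusted p = 4.41e-09) and was still lower at 48 h (-0.30 ± 0.049, adjusted p = 5.55e-05). The 1110 changed genes numbered 717 without the 2 h replicate 2 and 700 without the 2 h replicate 3.

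Immediate early genes were among those that fell at 2 h. Of the genes named next, Errfi1, Dusp6 and Lep are not in the immediate early list. Errfi1, an inhibitor of the EGF receptor, changed by -1.81 ± 0.095 (adjusted p = 3.25e-12), the MAP kinase phosphatase Dusp6 by -1.78 ± 0.17 (adjusted p = 1.21e-07) and the zinc finger factor Egr1 by -1.70 ± 0.30 (adjusted p = 0.000572). Ccn1, a matricellular target of YAP signalling, changed by -1.64 ± 0.25 (adjusted p = 7.96e-05), and the factor Klf6 by -1.35 ± 0.11 (adjusted p = 6.59e-09). Lep, which encodes the satiety hormone leptin, changed by -1.19 ± 0.24 (adjusted p = 0.00203) and by -1.79 ± 0.24 at 12 h (adjusted p = 4.99e-06), and its call at 2 h ended without replicate 2 of every group (-1.10, adjusted p = 0.124). Of the 25 immediate early genes, 14 fell and 11 did not change, against 17 lower and 2 higher adjusted over the list alone (median -0.44; camera adjusted p = 5.82e-14, and 0.013 with an estimated correlation). At 48 h the same list was mixed, with 5 higher and 8 lower genes (camera adjusted p = 0.55). Several genes of the unfolded protein and amino acid stress response were also lower at 2 h, with 7 of 18 called, or 9 lower and 1 higher adjusted over the list alone (camera adjusted p = 8.36e-06, and 0.0193 with an estimated correlation). Sesn2 and Chac1, induced by amino acid stress, changed by -0.70 ± 0.083 and -0.71 ± 0.092 (adjusted p = 2.86e-06 and 8.91e-06). At 48 h, 2 members of this stress list rose and 5 fell (camera adjusted p = 0.608), with a median above 0 and a mean below it.

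**Figure D2:**
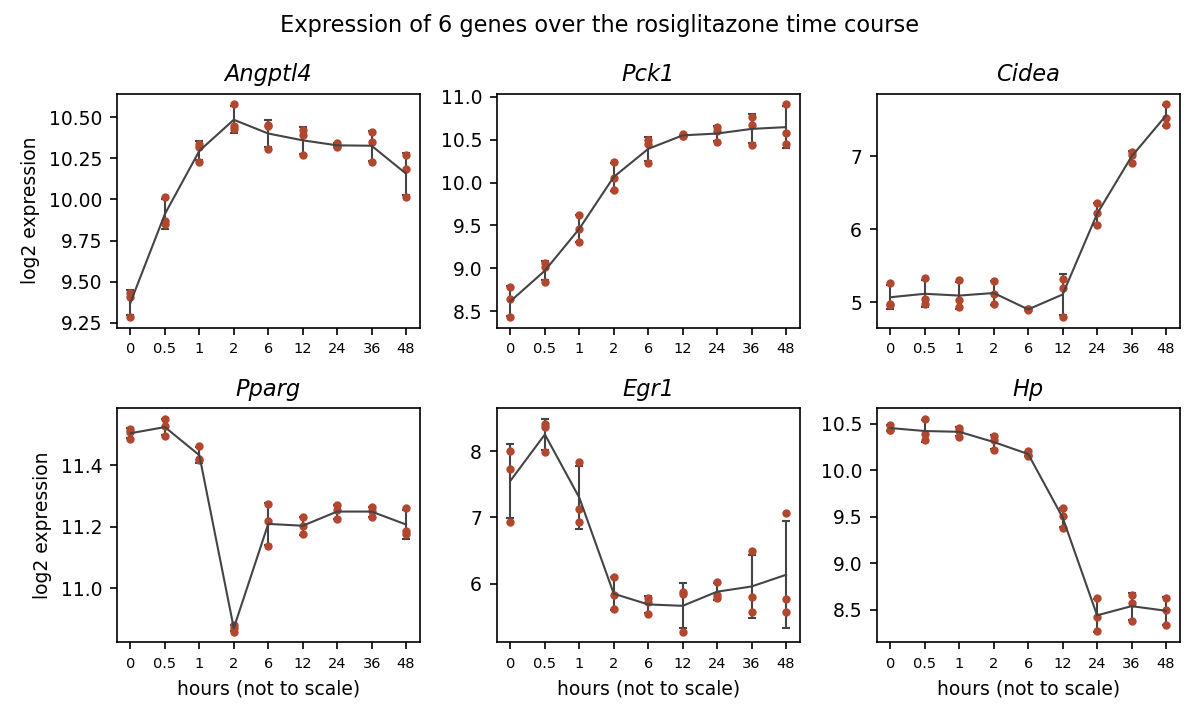
Log2 expression of 6 genes in the 27 arrays over the exposure, with hours on an axis that is not to scale. Points are arrays, and lines join group means with bars of 1 SD (n = 3). Angptl4 and Pck1 rose within 2 h, Cidea rose late, Egr1 fell within 2 h, Hp fell late, and Pparg was lowest at 2 h.

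At 6 h 1575 genes rose and 1536 fell, and at 12 h 1781 rose and 1761 fell. Pck1 reached 1.78 ± 0.11 at 6 h (adjusted p = 1.3e-10) and 1.93 ± 0.11 at 12 h (adjusted p = 3.19e-11). Arxes1, an adipocyte-related PPARγ target, rose by 1.31 ± 0.15 at 6 h (adjusted p = 7.03e-07), although its probes may also read its close paralog Arxes2. Elovl3, an enzyme of fatty acid elongation typical of brown fat, rose by 1.88 ± 0.24 at 12 h (adjusted p = 2.6e-06). Olr1, a scavenger receptor for oxidised lipoprotein, rose by 1.06 ± 0.22 at 6 h (adjusted p = 0.000981) and 1.53 ± 0.22 at 12 h (adjusted p = 1.09e-05). Among the decreases at 6 h, Ccn1 changed by -2.12 ± 0.25 (adjusted p = 1.1e-06), the Ras family gene Rasl11a by -1.80 ± 0.10 (adjusted p = 2.79e-11), and the differentiation inhibitor Id2 by -1.55 ± 0.27 (adjusted p = 0.000173). Adamts1 and Adamts5, proteases that cut matrix proteoglycans, changed by -1.59 ± 0.11 and -1.47 ± 0.093 (adjusted p = 5.3e-10 and 1.3e-10). Acta2, smooth muscle actin, changed by -1.53 ± 0.12 at 12 h (adjusted p = 2.66e-09).

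Of 27 measured PPARγ target genes of lipid storage and handling, 7 rose at 2 h, 15 at 6 h, 18 at 24 h and 14 at 48 h, and none fell at these times over all genes. Adjusted over the list alone, 18 were higher and 1 lower at 24 h. The list was higher at 24 h by camera (median 0.28, adjusted p = 1.17e-12, and adjusted p = 0.046 with an estimated correlation). Its calls at 2 h (adjusted p = 1.57e-08) and 48 h (adjusted p = 7.39e-07) were lost there (adjusted p = 0.093 and 0.118 with an estimated correlation). At 24 h, Pck1 was higher by 1.95 ± 0.11 (adjusted p = 7.44e-12), Pdk4 by 1.58 ± 0.11 (adjusted p = 9.29e-11) and the lipid droplet protein Hilpda by 1.29 ± 0.093 (adjusted p = 2.21e-10). Fabp4, the abundant fatty acid binding protein of fat cells, rose by 0.28 at 24 h (adjusted p = 0.00139, and 0.25 with adjusted p = 0.0848 without replicate 2 of every group), while its change of 0.17 at 48 h was not called (adjusted p = 0.0557). Adipoq, which encodes adiponectin, was not called at 24 h (0.11, adjusted p = 0.184) or 48 h (-0.089, adjusted p = 0.264). Between 24 h and 48 h this list had a median of -0.076 and a mean of 0.0022, and camera called it lower (adjusted p = 0.0434, and adjusted p = 0.512 with an estimated correlation), although 2 members rose and none fell.

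Many genes of fatty acid oxidation rose. Of 18 mitochondrial members, 14 rose at 24 h and 4 did not change, with the same 14 as the count adjusted over the list alone (camera adjusted p = 1.95e-09, and adjusted p = 0.104 with an estimated correlation). The trifunctional protein genes Hadhb and Hadha rose by 0.82 ± 0.073 and 0.54 ± 0.065 (adjusted p = 6.87e-09 and 6.54e-07), and the carnitine carrier Slc25a20 by 0.90 ± 0.11 (adjusted p = 8.27e-07). Of 14 peroxisomal members, 8 rose at 48 h and 1 fell, as they did adjusted over the list alone (camera adjusted p = 0.00149, and adjusted p = 0.129 with an estimated correlation). The peroxisomal thiolase Acaa1b had the largest increase at 48 h, 2.62 ± 0.20 (adjusted p = 3.7e-10), although its probes may also read Acaa1a (0.54 ± 0.072, adjusted p = 2.35e-06). Abcd2, a peroxisomal importer of very long chain fatty acids, changed by -1.02 ± 0.13 (adjusted p = 1.06e-06). Of 34 oxidative phosphorylation genes, 14 rose at 36 h and 9 at 48 h, against 16 and 10 adjusted over the list alone. Their camera calls (adjusted p = 7.39e-07 and 0.00138) were lost, with adjusted p = 0.179 and 0.428 with an estimated correlation. Sdhd, a subunit of complex II, rose by 0.37 ± 0.061 at 48 h (adjusted p = 4.55e-05).

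Many thermogenic genes, typical of brown and beige fat, were higher at the late times. Of 17 measured members, 1 rose at 2 h, 3 at 12 h, 8 at 24 h and 10 at 48 h, when 1 fell and 6 did not change, with the same counts adjusted over the list alone (median 0.42; camera adjusted p = 7.87e-06, and 0.0252 with an estimated correlation). Cidea, a lipid droplet protein abundant in brown fat, rose by 2.49 ± 0.12 at 48 h (adjusted p = 2.55e-13). Cox7a1 and Cox8b, muscle and brown fat subunits of cytochrome oxidase, rose by 1.40 ± 0.089 and 0.83 ± 0.081 (adjusted p = 1.41e-11 and 2.35e-08). Elovl3 was higher by 2.33 ± 0.24 (adjusted p = 4.88e-08), and Ppargc1a, the coactivator of mitochondrial biogenesis, by 0.93 ± 0.14 (adjusted p = 9.21e-06). Ucp1, the uncoupling protein that makes brown fat produce heat, showed no detectable change (0.0025, adjusted p = 0.988) and lay near the floor with a mean of 2.78. Slc29a1, a nucleoside transporter, was the member that fell (-0.80 ± 0.081 at 24 h, adjusted p = 6.55e-08).

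**Figure D3:**
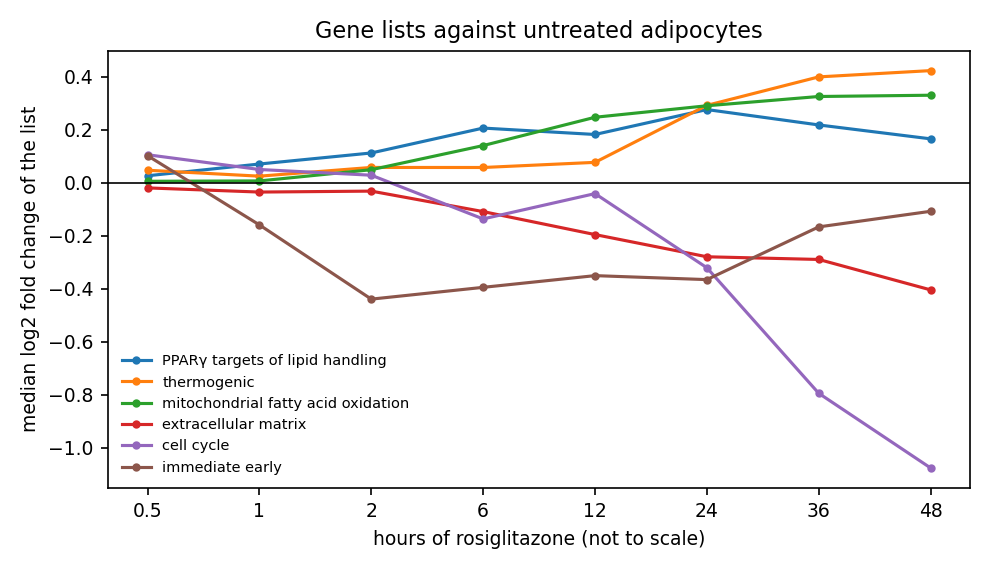
Median log2 fold change against untreated adipocytes of 6 gene lists at 8 times, with hours on an axis that is not to scale. Each line is 1 list of genes. The cell cycle list reached -1.08 and the thermogenic list 0.42 at 48 h, while the immediate early list was lowest at 2 h, at -0.44.

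Many lipid synthesis genes were lower at 48 h. Of 18 genes of de novo lipogenesis, 11 fell and 2 rose at 48 h, over all genes and adjusted over the list alone (camera adjusted p = 0.000113, and adjusted p = 0.0993 with an estimated correlation). Elovl6, which elongates palmitate, changed by -1.24 ± 0.12 (adjusted p = 2.16e-08), and Acly, which supplies cytosolic acetyl-CoA, by -0.57 ± 0.056 (adjusted p = 3.21e-08). Acacb, the acetyl-CoA carboxylase that restrains oxidation, rose by 0.60 ± 0.081 (adjusted p = 3.07e-06). Of 18 cholesterol synthesis genes, 11 fell at 48 h and none rose, against 13 lower adjusted over the list alone (camera adjusted p = 1.11e-06, and adjusted p = 0.104 with an estimated correlation). The sterol carrier Stard4 changed by -0.89 ± 0.097 (adjusted p = 1.32e-07) and Cyp51, an enzyme of lanosterol demethylation, by -0.49 ± 0.079 (adjusted p = 3.72e-05).

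Several acute-phase and inflammatory genes were lower at 24 h and 48 h. Hp, the haemoglobin scavenger haptoglobin, changed by -2.02 ± 0.088 at 24 h (adjusted p = 7.52e-14), and Orm2, an acute-phase glycoprotein, by -2.49 ± 0.17 (adjusted p = 1.42e-10), although Orm2 probes may also read Orm1. The adhesion molecule Vcam1 changed by -1.13 ± 0.10 (adjusted p = 9.98e-09), and the macrophage growth factor Csf1 by -1.003 ± 0.10 (adjusted p = 7.79e-08). The chemokine Ccl6 changed by -2.56 ± 0.24 at 48 h (adjusted p = 1.19e-08) and Ccl2, which draws monocytes, by -1.15 ± 0.16 (adjusted p = 6.36e-06). Orm2 and Ccl6 are not in the inflammatory and acute-phase list. Of its 21 measured members, 7 fell and 1 rose at 24 h, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.000526, and 0.0373 with an estimated correlation). At 48 h 8 fell and 3 rose (camera adjusted p = 0.00736, and adjusted p = 0.0892 with an estimated correlation). Several interferon response genes were lower at 24 h, with 8 of 18 lower and 2 higher, or 12 and 2 adjusted over the list alone (camera adjusted p = 0.00432, and adjusted p = 0.0892 with an estimated correlation). Psmb8 and Psmb9, subunits of the immunoproteasome, changed by -0.69 ± 0.12 and -0.48 ± 0.083 (adjusted p = 0.000172 and 9.25e-05).

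Of 28 extracellular matrix genes, 15 fell at 12 h, 17 at 24 h and 22 at 48 h, when none rose and 23 were lower adjusted over the list alone (median -0.40; camera adjusted p = 2.05e-14, and 0.000879 with an estimated correlation). The proteoglycan Lum changed by -1.16 ± 0.12 at 48 h (adjusted p = 6.15e-08), the membrane protease Mmp14 by -0.66 ± 0.060 (adjusted p = 7.44e-09), and the matricellular protein Sparc by -0.54 ± 0.059 (adjusted p = 1.16e-07). Pcolce2, an enhancer of collagen maturation, changed by -2.17 ± 0.12 (adjusted p = 1.96e-12). Of 19 preadipocyte and fibroblast markers, 9 fell, 1 rose and 9 did not change at 48 h, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.000311, and adjusted p = 0.16 with an estimated correlation). Acta2 changed by -2.37 ± 0.12 (adjusted p = 4.66e-13), the calcium-binding protein S100a4 by -1.38 ± 0.11 (adjusted p = 1.45e-09) and the preadipocyte marker Dlk1 by -0.73 ± 0.073 (adjusted p = 3.12e-08), while the mesenchymal factor Twist2 rose by 0.82 ± 0.080 (adjusted p = 2.16e-08).

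Of 20 cell cycle genes, none changed at 2 h, 3 fell at 6 h, 2 fell and 1 rose at 12 h, 13 fell at 24 h, 18 at 36 h and 19 at 48 h, again 19 adjusted over the list alone (median -1.08; camera adjusted p = 5.49e-21, and 0.0252 with an estimated correlation). The 3 calls at 6 h depended on the setting: Top2a changed by -0.49 there but by -0.032 when its probe sets were averaged (adjusted p = 0.866), and the call of Mki67 ended under median centring (-0.33, adjusted p = 0.108). The call of the mitotic kinase Aurkb (-0.38 at 6 h) ended without replicate 2 or 3 of every group (-0.36 and -0.33, adjusted p = 0.073 and 0.0639), where 2 arrays per group remained. Cyclin A2 (Ccna2) changed by -2.01 ± 0.12 at 48 h (adjusted p = 6.81e-12), the proliferation marker Mki67 by -1.99 ± 0.14 (adjusted p = 9.75e-11) and the topoisomerase Top2a by -1.68 ± 0.13 (adjusted p = 6.8e-10). Between 24 h and 48 h, 134 genes rose and 140 fell, and 13 of the 20 cell cycle genes fell (median -0.51; camera adjusted p = 1.36e-30, and 0.00935 with an estimated correlation), or 16 adjusted over the list alone. In that interval Cidea rose by 1.35 ± 0.12 (adjusted p = 4.13e-07) and Aqp8, a water and peroxide channel, by 1.18 ± 0.11 (adjusted p = 6.89e-07), while Ccnb2, a mitotic cyclin, changed by -1.33 ± 0.13 (adjusted p = 6.31e-07). The 274 genes called in this interval numbered 87, 132 and 154 without the 24 h replicate 1, 2 or 3, and 106 without the 48 h replicate 3. They numbered 28 when only the 6 arrays compared entered the model. Centring each array on its median moved the rising share here from 48.9% to 33.7%.

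Other regulators and secreted factors moved both ways. Of 21 adipocyte transcription factors and cofactors, 5 rose and 6 fell at 48 h, or 6 and 8 adjusted over the list alone (camera adjusted p = 0.46): Ppargc1b, a coactivator of oxidative genes, rose by 0.70 ± 0.085 (adjusted p = 6.43e-07) and Klf15 changed by -0.59 ± 0.070 (adjusted p = 5.04e-07). Of 15 secreted adipokines, 5 rose and 5 fell at 48 h, also adjusted over the list alone (camera adjusted p = 0.274), with the growth factor Igf1 at -0.82 ± 0.074 and the hormone precursor Agt at -0.86 ± 0.072 (adjusted p = 6.12e-09 and 1.95e-09). Of 21 genes of insulin signalling and glucose uptake, 7 rose and 5 fell at 48 h, or 7 and 7 adjusted over the list alone (camera adjusted p = 0.927), with a median of 0.083 and a mean of -0.024. Pik3r1, a regulatory subunit of PI3 kinase, changed by -0.86 ± 0.076 (adjusted p = 4.85e-09), while the glucose transporter Slc2a1 rose by 0.36 ± 0.068 (adjusted p = 0.000287). Of 20 genes of branched-chain amino acid breakdown, 4 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.433), with Ivd at -0.58 ± 0.060 (adjusted p = 6.26e-08). Of 11 lipolysis and adrenergic genes, 8 rose at 24 h, also adjusted over the list alone (camera adjusted p = 0.000208, and adjusted p = 0.115 with an estimated correlation), led by the glycerol channel Aqp7 (0.62 ± 0.074, adjusted p = 7.01e-07).

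Of 17 glucocorticoid-responsive genes, 2 rose and 7 fell at 6 h, or 2 and 9 adjusted over the list alone (camera adjusted p = 0.00104, and 0.0487 with an estimated correlation). At 24 h that list had a median of 0.028 and a mean of -0.15, and camera gave the lower direction (adjusted p = 0.256). Fkbp5, a chaperone induced by glucocorticoids, changed by -0.82 ± 0.094 at 48 h (adjusted p = 2.76e-07), and the sulfotransferase Sult1a1 by -1.09 ± 0.11 (adjusted p = 3.92e-08). Of 10 reference genes, 3 rose and 5 fell at 48 h, or 3 and 6 adjusted over the list alone (camera adjusted p = 0.253). Gusb changed by -0.71 ± 0.087 (adjusted p = 7.74e-07), Actb by -0.34 ± 0.050 (adjusted p = 1.14e-05), and Hprt rose by 0.39 ± 0.077 (adjusted p = 0.000458).

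The intervals within the course, which do not use the untreated arrays, showed when genes turned. From 2 h to 6 h 1720 genes changed: the vasodilator peptide Adm rose by 1.26 ± 0.17 (adjusted p = 1.94e-05), the fatty acid receptor Ffar4 rose by 0.86 ± 0.090 (adjusted p = 9.93e-07), and the nuclear receptor Nr4a1 changed by -1.46 ± 0.20 (adjusted p = 1.85e-05). That count was 1119 without the 2 h replicate 1 and 1119 without the 2 h replicate 2, and median centring moved its rising share from 46.6% to 71.4%. From 6 h to 24 h 2164 genes changed, among them the hypoxia-responsive gene Ndrg1 (1.68 ± 0.14, adjusted p = 8.74e-09) and Hp (-1.74 ± 0.088, adjusted p = 2.49e-12). From 2 h to 48 h 4448 genes changed: Depp1, a FOXO target, rose by 2.62 ± 0.13 (adjusted p = 3.98e-13), Adm by 2.60 ± 0.17 (adjusted p = 2.73e-11), the glycolytic enolase Eno2 by 2.39 ± 0.12 (adjusted p = 6.02e-13) and the carbonic anhydrase Car9 by 1.99 ± 0.12 (adjusted p = 5.63e-12).

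Many genes that rose early were lower at 48 h than at 2 h. Of 589 genes that rose at 1 h or 2 h, 271 were lower and 53 higher at 48 h than at 2 h, while at 48 h 267 were higher and 50 lower than untreated. Rasl11b was lower at 48 h than at 2 h by -1.52 ± 0.11 (adjusted p = 6.81e-11) and the potassium channel Kcnh4 by -1.55 ± 0.17 (adjusted p = 1.11e-07). A lower value than at 2 h need not be a return to the untreated level. Angptl4 changed by -0.33 from 2 h to 48 h but was still 0.785 above untreated at 48 h. Of 572 genes that fell at 1 h or 2 h, 264 were higher and 49 lower at 48 h than at 2 h, while 62 were higher and 238 lower than untreated. Both calls used the 2 h arrays, so a gene picked for a high value at 2 h is called lower later more often by chance.

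Genes called at one time were often called at another. At 2 h and 24 h, 486 genes changed in the same direction and 92 in opposite directions, with 258 higher at both against 57.8 expected and 228 lower at both against 56.8 expected. At 6 h and 24 h the numbers were 1812 and 35, with 896 higher against 159.4 expected and 916 lower against 161.8 expected. At 24 h and 48 h they were 2920 and 1, with 1469 higher against 240.1 expected and 1451 lower against 225.7 expected. In 20 simulations every array, the untreated ones included, was drawn around each gene's mean, and 0 shared genes were called. Such data without changed genes give few calls at any time. The simulations therefore do not show how far shared controls raise the overlaps. The 3 untreated arrays cannot be split between the comparisons, so part of the excess may come from the shared controls. Pck1 and Angptl4 were among the genes higher at 2 h, 24 h and 48 h.

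Several clock genes alternated between the late exposure times, which lay 12 h apart. Only hours of exposure were used, so the clock time of each harvest was not known here. The mean of 24 h and 48 h minus that of 12 h and 36 h was -0.75 for the activator Npas2 (SE 0.076, adjusted p = 9.11e-06), 0.53 for the repressor Per2 (adjusted p = 6.77e-05) and 0.58 for its relative Per3 (adjusted p = 5.61e-05). The activator Arntl gave -0.32 (adjusted p = 0.00238), Cry1 0.26 (adjusted p = 0.0232) and Nr1d2 0.35 (adjusted p = 0.0336), the latter 2 named after their values were seen. These were 6 of 17 measured clock genes, beside 430 called among all genes tested. The contrast also takes up steady change. Cidea, called at 0.83 (adjusted p = 9.11e-06), rose throughout, with means of 5.1, 6.2, 7.0 and 7.6 from 12 h to 48 h. Counts of genes that alternated therefore include genes with a steady change. Without replicate 2 of every group, Per2 (0.43) and Per3 (0.53) had an adjusted p of 0.0514, Arntl (-0.27) 0.162, Cry1 (0.20) 0.334 and Nr1d2 (0.39) 0.217, while the call of Npas2 held in each of the 3 models that left out a replicate. Without replicate 1, Cry1 (0.28) had an adjusted p of 0.14 and Nr1d2 (0.22) 0.231, and without replicate 3 Arntl (-0.35) had 0.059 and Nr1d2 (0.44) 0.0788. These models leave 2 arrays per group, and several of the differences did not shrink in them. Nr1d2 had 0.13 and an adjusted p of 0.237 when a gene's probe sets were averaged. With the linear and quadratic trend over the 4 groups removed, 4 genes were called, 3 of them clock genes: Npas2 at -0.61, Per2 at 0.50 and Per3 at 0.55 (adjusted p = 0.00267 for each). The calls of the other 3 ended there: Arntl kept its size but not its call (-0.32, adjusted p = 0.0576), Cry1 had 0.19 (adjusted p = 0.42) and Nr1d2 0.25 (adjusted p = 0.451). Against untreated cells, 2 of the 17 clock genes rose and 6 fell at 2 h, or 3 and 9 adjusted over the list alone (camera adjusted p = 0.000133, and adjusted p = 0.0913 with an estimated correlation). Per1, a clock gene that also answers to stimuli, changed by -0.89 ± 0.12 at 2 h (adjusted p = 1.28e-05).

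**Figure D4:**
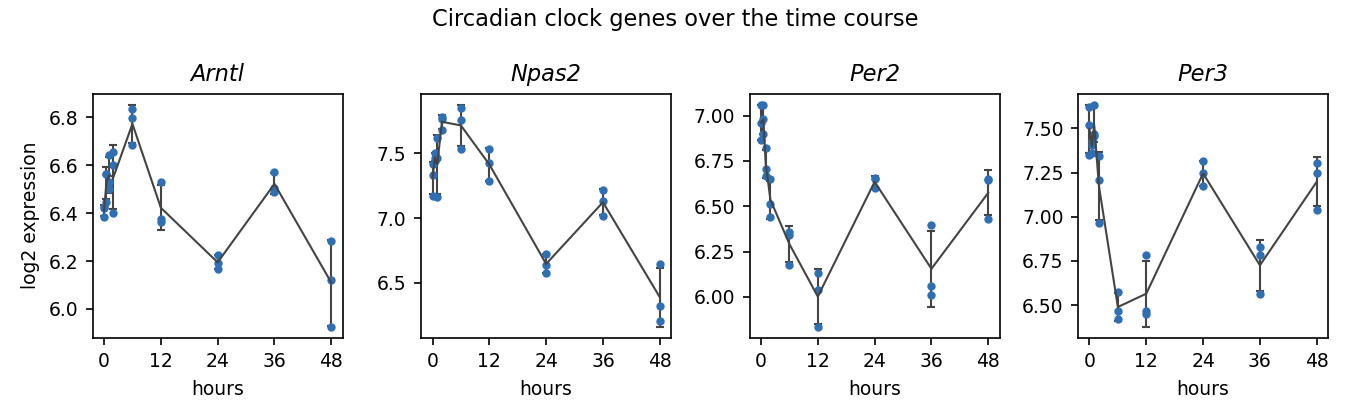
Log2 expression of the clock genes Arntl, Npas2, Per2 and Per3 in the 27 arrays against hours of rosiglitazone. Points are arrays, and lines join group means with bars of 1 SD (n = 3). Per2 and Per3 were higher at 24 h and 48 h than at 12 h and 36 h on average (differences of 0.53 and 0.58).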

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

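Of the tests in this part, the removal of the trend from the alternation and the check of markers from 24 h to 48 h were chosen only after the results were seen.

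At 48 h, 19 of 20 cell cycle genes, 22 of 28 extracellular matrix genes and 9 of 19 preadipocyte and fibroblast markers were lower than untreated, although the camera call of the markers was lost with an estimated correlation (adjusted p = 0.16). A smaller share of undifferentiated cells would lower all their markers alike only if the adipocytes neither expressed nor regulated them, which was not tested. Of 12 markers with a mean above that of the median gene, 1, Twist2, rose, while 7 fell (median of the 12 -0.38). In advance, 2 or more rising markers had been set to exclude a smaller share, and that number was not reached. From 24 h to 48 h, when cell cycle genes had a median of -0.51, the 12 markers had a median of 0.025 but went both ways, with Dlk1 lower by -0.34 (adjusted p = 0.0149, not called after quantile normalization at 0.0599 or without replicate 1, 2 or 3 at 0.0556, 0.247 and 0.179), which decides nothing, so this explanation stays open. An effect of time in culture without the drug cannot be told apart from the drug's, since 0 vehicle arrays were among the samples. An effect of rosiglitazone on these genes, the biological explanation in the design, also stays open.

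Several clock genes changed over the time course. A daily rhythm in the cultures may account for part of this: the median absolute alternation of the 17 clock genes (0.25) was above that of 100% of 10000 random lists matched on mean expression, whose median was 0.070. Random lists do not carry the correlation among genes of a list, so this share overstates the evidence where clock genes move together. With the linear and quadratic trend removed, 4 genes were called in place of 430, and 3 of those 4 were Npas2, Per2 and Per3. The fourth, Tas2r107, a taste receptor gene named after its value was seen, changed by -0.32 (adjusted p = 0.00635). If harvests followed the hours of exposure, a daily rhythm would place time 0 with 24 h and 48 h. Per2 (6.96) and Per3 (7.50) at time 0 lay nearer their means at 24 h and 48 h than at 12 h and 36 h. Npas2 (7.31) lay nearer 12 h and 36 h (7.41 and 7.12) than 24 h and 48 h (6.65 and 6.39), as did Arntl (6.41). Time 0 thus went both ways and does not decide. An effect of the drug on the clock was not tested apart from a rhythm set by handling.

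At 2 h, 14 of 25 immediate early genes were lower than untreated, and at 48 h 8 were lower and 5 higher. If the untreated arrays alone had been high, for example from handling at time 0, these 14 would not fall from 30 min, but they had a median change of -0.92 against the 30 min arrays, beside -0.79 against untreated, and 13 of them fell against 30 min as well. The untreated arrays were thus not alone in being high, since the 30 min arrays were high too. But the immediate early list was higher at 30 min than untreated by camera with the preset correlation, so a fall from 30 min could follow from that rise. The 14 genes were also picked for low values in the same 2 h arrays. The check therefore does not decide whether handling had raised the untreated arrays. A shift with time in culture or handling cannot be told apart from the drug, since 0 vehicle arrays were among the samples.

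A total of 103 genes were called in opposite directions at 2 h and 48 h against untreated, with 56 lower and then higher and 47 higher and then lower. The difference between both times was tested directly in the comparison of 48 h with 2 h (limma adjusted p, n = 3). It was 2.62 for Depp1 (adjusted p = 3.98e-13), 2.60 for Adm (adjusted p = 2.73e-11) and 2.39 for Eno2 (adjusted p = 6.02e-13). It was -1.80 for the methyltransferase-like gene Mettl7b (adjusted p = 1.65e-10) and -1.66 for the oxidative stress gene Osgin1 (adjusted p = 1.05e-09), and Mettl7b was named after its value was seen. Outside the genes tested in the report, 7662 probe sets carried no symbol or several, and 764 of them (9.97%) were called at 48 h against untreated, 367 higher and 397 lower.

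Each comparison of 2 groups was refitted on the 10 ways of splitting its 6 arrays, which are too few for a share under 0.05, and in each of the 12 comparisons 1 split, the real one, gave as many genes. Against untreated, the real counts of 9, 186, 1110, 3111, 3542 and 3879 from 30 min to 24 h stood beside 0 in the highest other split. At 36 h 4022 stood beside 420, and at 48 h 4515 beside 2. Within the course, 1720 stood beside 0 for 6 h against 2 h, 2164 beside 1 for 24 h against 6 h, 274 beside 2 for 48 h against 24 h and 4448 beside 0 for 48 h against 2 h. For results over several groups, 100 regroupings were drawn. Mixing arrays of different times adds the differences between times to the spread within groups, which lowers the other counts. The arrays may also be technical replicates, so these numbers do not exclude chance. As many genes changed over the course in 1 of them, the real one (7613, highest other 11), and as many early induced genes were lower later in 1 (271, highest other 137). Regrouping also removes the early rise itself. It therefore does not show that these genes were lower later beyond what their choice by 2 h values brings. As many genes were called for alternation in 2 of them, the real one (430) and another (1095). What set that other regrouping apart was not examined. Steady change over the 4 times also enters this contrast, as 4 genes were called with the linear and quadratic trend removed.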

How the results depend on the processing

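The settings that leave out single arrays, take the 30 min arrays as the baseline, leave out the 36 h group or remove the trend were chosen only after the results were seen. Values of genes covered by the naming rule, with the clock and hypoxia genes, numbered 12754 over 10 settings planned in advance. Of these, 12161 kept their call or lack of one, 430 lost their call, 163 gained one and 0 reversed. A reversal was counted only where a fit called the gene, so the signs of genes called in neither fit were not compared. Most lost calls, 87, 146 and 119, came without replicate 1, 2 or 3, where 2 arrays per group remained. Unless stated, the cause of a shift was not tested.

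With the replicate number as a block, 118 genes were called at 1 h, 156 at 48 h against 24 h, and 194 alternated. Arrays of the same number shared no common shift on average, and the order of the numbers changed direction with time, which a block does not take up. Whether effects are weaker cannot be told from these lower counts. With genes above the median mean alone, 647 alternated. Array weights gave 21 genes at 30 min, 292 at 1 h, 1854 at 2 h, 6318 at 36 h, 551 at 48 h against 24 h, 903 that alternated and 407 that were lower later. The 36 h arrays had the weights 0.335, 0.47 and 3.88, so the 36 h value rested mainly on replicate 3.

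Requiring a change of at least 1.5-fold lowers counts by construction. It left 4 genes at 30 min, 49 at 1 h, 200 at 2 h, 385 at 6 h, 474 at 12 h, 681 at 24 h, 758 at 36 h and 810 at 48 h. It left 166 for 6 h against 2 h, 255 for 24 h against 6 h, 37 for 48 h against 24 h, 831 for 48 h against 2 h, 11 that alternated, 1311 over the course and 38 lower later. Shared genes were then 58 for 2 h and 24 h, 225 for 6 h and 24 h, and 533 for 24 h and 48 h. Models of only the 6 arrays compared gave 3 genes at 30 min, 2618 at 36 h and 28 at 48 h against 24 h.

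Without replicate 1, 2 or 3 of every group, or without single arrays, fewer arrays enter and the counts mostly fall. They ranged from 2 to 12 at 30 min, 35 to 143 at 1 h, 448 to 883 at 2 h, 1503 to 2591 at 6 h, 1813 to 3137 at 12 h, 2223 to 3647 at 24 h, 2665 to 3812 at 36 h and 2672 to 3959 at 48 h. They ranged from 587 to 1380 for 6 h against 2 h, 814 to 1886 for 24 h against 6 h, 40 to 314 for 48 h against 24 h and 2725 to 4006 for 48 h against 2 h. The ranges were 30 to 149 for alternation, 4690 to 5969 over the course and 108 to 189 for genes lower later. Single arrays moved a count by over 1.5 times at 1 h (96, 122 and 109 without untreated replicate 1, 2 or 3, and 82 without the 1 h replicate 3). They did so at 2 h (717 and 700 without its replicate 2 or 3), for 6 h against 2 h (1119 without the 2 h replicate 1 and 1119 without replicate 2) and for 48 h against 24 h (87, 132 and 154 without the 24 h replicate 1, 2 or 3, and 106 without the 48 h replicate 3). With the 30 min arrays as the baseline, 117 genes were called at 1 h. With the linear and quadratic trend removed, 4 genes alternated.

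Camera with an estimated correlation called 0, 0, 3, 2, 3, 4, 4 and 3 lists from 30 min to 48 h, in place of 4, 5, 10, 14, 14, 12, 14 and 11 with the preset one. Fry called 3, 6, 11, 14, 15, 14, 16 and 16.

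Median centring moved the share of rising genes among those called from 50.6% to 76.5% at 6 h, 50.3% to 68.2% at 12 h, 49.0% to 70.4% at 24 h, 50.9% to 72.6% at 36 h and 52.5% to 65.9% at 48 h. It moved the share from 46.6% to 71.4% for 6 h against 2 h and from 48.9% to 33.7% for 48 h against 24 h, while the median of all genes shifted by at most 0.086. After a further quantile normalization the share was 52.15% at 6 h and 50.9% at 48 h. It was then 50.4% for 6 h against 2 h and 45.4% for 48 h against 24 h. Among 128 camera calls of lists, the sign of the median changed in 1 under centring (extracellular matrix at 6 h against 2 h, from -0.058 to 0.0046) and in 1 under quantile normalization (PPARγ targets at 24 h against 6 h, from 0.025 to -0.00062). The arrays' signal over background limits genes near the floor, such as Ucp1, for which a lack of change is not shown.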

Other observations

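The pattern below was noticed in the results, the test of the held-out list was written before the values of its genes were seen, and the test of handling was chosen only after the results were seen.

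Several genes that were lower at 2 h and higher at 48 h than untreated, such as Adm and Eno2, are known to answer to low oxygen. A shift of hypoxia-responsive genes may underlie this, and it was tested on 35 such genes whose values had not been looked at, 32 of them measured. Their median change was -0.080 at 2 h, above that of 0% of 10000 random lists matched on mean expression, and 0.32 at 48 h against 2 h, above that of 100%. At 48 h against untreated it was 0.19, above 99.99% of the random lists. Random lists do not carry the correlation among genes of a list, so these shares overstate the evidence where such genes move together. Of the 32 genes, 5 fell and 0 rose at 2 h, 19 rose and 0 fell from 2 h to 48 h, and 16 rose and 0 fell at 48 h. These genes are named here after their values were seen: the histone demethylase Kdm3a changed by -0.49 at 2 h (adjusted p = 0.000291) and by 0.76 from 2 h to 48 h. Kdm3a, with Narf and Slc16a3, was also among the genes called in opposite directions at 2 h and 48 h. That is the pattern behind the test, so these genes give it no separate support. The shares and counts above include them, and they are among the 5 genes that fell at 2 h. The oxygen sensor Egln1 was higher by 0.54 at 48 h (adjusted p = 4.38e-06), and the phosphofructokinase Pfkp by 0.90 (adjusted p = 4.94e-08). Among 20 further hypoxia genes whose values had been seen first, 13 fell and 2 rose at 2 h, and 17 rose from 2 h to 48 h. The shift at 2 h was small. Handling or the oxygen supply of the cultures cannot be told apart from the drug as its source, since 0 vehicle arrays were among the samples.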
